A study of Oryctolagus cuniculus with 20 samples.

How the data were processed

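The series holds 20 RNA sequencing libraries of rabbit vessels, total RNA extracted with TRIzol and read in pairs on a NovaSeq X Plus. Per the submitters' processing notes, the authors used fastp, HISAT2, StringTie, RSEM and DESeq2, with no version and no genome build given in the sources used here. The authors deposited 1 table of FPKM (fragments mapped per kilobase of transcript, scaled to the depth of the library) with 24964 transcript rows and no read counts, so the depth per library and counting errors are unknown.

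Transcripts were summed to 23669 genes, of which 1278 had more than 1 transcript, and 7195 were at 0 in all libraries. Genes with at least 1 FPKM in at least 4 libraries were kept, 8657 in all: 6824 with a symbol in the table, 618 named through their NCBI gene number in a table of rabbit gene symbols, and 1215 without a symbol, which were counted and not named. Sums of FPKM per library ran from 327806 to 671582.

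Groups were taken from the labels, 4 libraries each. limma with a mean per group over all 20 libraries, on log2(FPKM + 1), with moderated variances that follow the mean level, tested each contrast, and p-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. All tests were two-sided. Errors of log2 changes are limma's moderated standard errors, and errors of FPKM are SD. THBS4 was also tested by exact permutation. The contrasts were graft against control on each day, the difference of these, day 30 against day 14 within grafts and within controls, vein against the mean of both control groups, and each graft group against vein. Correlations across genes have jackknife errors over libraries.

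For 35 gene lists, limma's camera tested the members against all other genes with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. Of 104 list calls followed, the estimated correlation gave the highest adjusted p in 93.

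The tests, the lists, the other settings and the rule for named genes were fixed before the data were examined. The rule names the 8 largest rises and falls, or 6 for the contrasts between days, among genes with a symbol that passed, with a mean of at least 5 FPKM in the higher group and, except between days, no overlap between the groups. It adds up to 4 members per list with the smallest adjusted p, or up to 4 that did not pass where a list did not change, and always, among others, THBS1, THBS2, THBS3, THBS4, COMP, ACTA2, MYH11, TAGLN, CNN1, BAX and BCL2. Some genes that the rule names are not reported here.

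Settings chosen beforehand were a pseudocount of 0.1, a filter of 5 FPKM or none, median-of-ratios, TPM and quantile scaling, only the groups compared, library weights from limma (for each library or each group), each library left out, the replicate number as a block, and the estimated correlation. Added after seeing the data were control day 14 counted as 1 sample, the 4 mixture-like libraries left out, both together, 2 control day 30 libraries left out, and genes listed at 0 in any library left out. Other splits of the libraries were also fitted. A mixture was fitted as the weighted mean of the other 3 libraries of a group, with weights in steps of 0.05, over genes averaging at least 10 FPKM.

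The procedure was tested on simulated data with 200 changed genes. With the same spread in all groups, 6 of 121 calls were false for grafts against controls at day 14, and genes changed by 1 on the log2 scale were recovered in 59.1% of cases. With the spread each group shows, 41 of 155 calls were false there, and between 9.5% (vein) and 43.2% (grafts of day 30 against day 14) elsewhere. No unchanged list was called. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.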

Results

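Total RNA from rabbit (Oryctolagus cuniculus) blood vessels was sequenced in paired-end libraries. A piece of common carotid artery had been moved into a vein. The graft was collected on day 14 or day 30, each time with the opposite, unoperated carotid artery as the control. Unoperated vein formed the remaining group, for 5 groups of 4 libraries. The labels call the libraries of a group biological replicates and do not say that each comes from a separate animal, so the p-values measure the spread between samples. All samples also carry the cell line name HASMC, although the other labels describe rabbit tissue.

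Values are FPKM, so read numbers are unknown. Between 6759 and 7740 genes per library reached 1 FPKM, and 8657 genes were tested.

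Spread differed between groups. Over 1126 genes above 30 FPKM, the median SD of log2 values was 0.0696 in control day 14, against 0.307 in graft day 14, 0.186 in control day 30, 0.178 in graft day 30 and 0.130 in vein. In each of those 4 groups the library closest to a weighted mean of the other 3 was called mixture-like. Its median absolute log2 difference was 0.0749 (graft day 14 replicate 3) and 0.0829 (control day 30 replicate 2). It was 0.0812 (graft day 30 replicate 4) and 0.0739 (vein replicate 4). The others lay between 0.0979 (vein) and 0.305, those of control day 14 between 0.0723 and 0.0760. Counts are also given without the mixture-like libraries, with control day 14 as 1 sample and with both changes, all chosen after seeing the data. Of the genes tested, 1981 were listed at 0 in at least 1 library, 282 of them with 20 FPKM or more in another library, and a listed 0 can be a failed estimate.

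**Figure D1:**
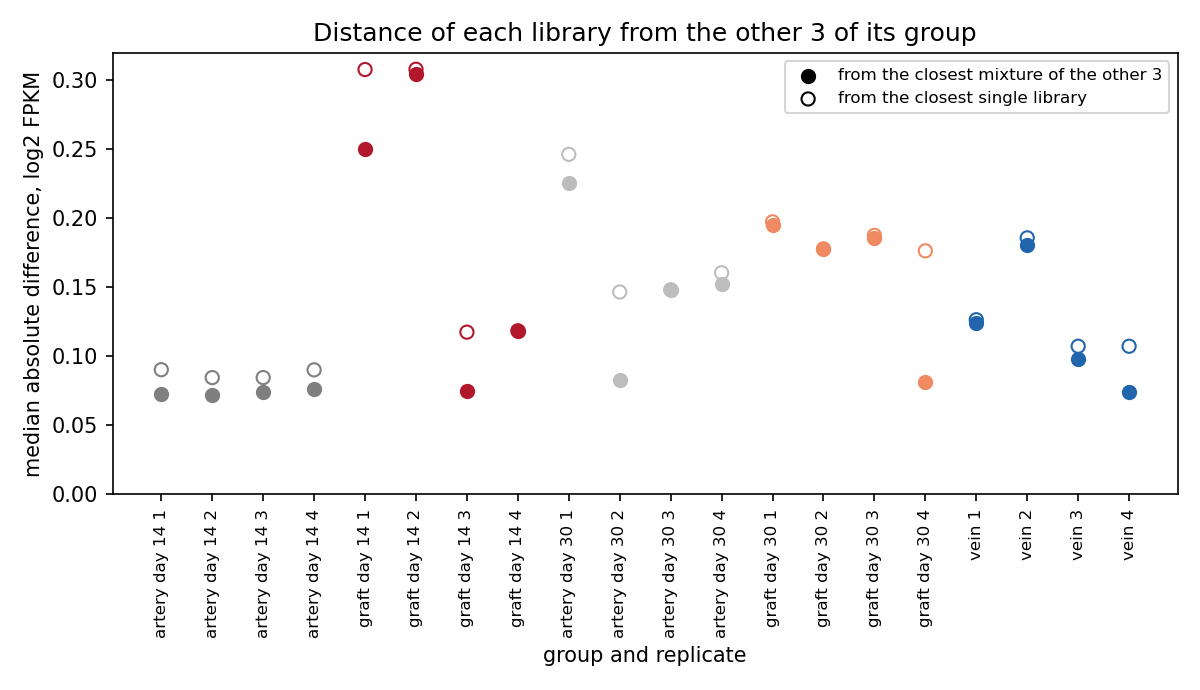
Median absolute log2 difference of each of the 20 libraries from the closest weighted mean of the other 3 libraries of its group (filled points) and from the closest of those libraries (open points).

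By day 14 most contractile genes (23 of 29, with 2 higher) were lower in the transplanted artery than in the opposite one, and most macrophage (18 of 21, with 1 lower), cell cycle (22 of 23) and matrix protease genes (17 of 26, with 3 lower) were higher. With an estimated correlation these list calls were lost (adjusted p = 0.0511, 0.274, 0.274 and 0.417). ACTA2, smooth muscle actin, fell from 7170 ± 115 to 641 ± 146 FPKM (mean ± SD, n = 4 libraries in each group), a log2 change of -3.51 (SE 0.15, adjusted p = 5.91e-12). PLN, phospholamban, which controls the calcium pump of the muscle's store, fell from 600 ± 6.11 to 28.9 ± 5.25 FPKM (log2 change -4.34, SE 0.12, adjusted p = 5.74e-14). MMP12, the elastase of macrophages, rose from 0.0675 ± 0.0287 to 374 ± 148 FPKM (log2 change 8.37, SE 0.30, adjusted p = 1.53e-12). The test called 4634 of 8657 genes, 3161 higher and 1473 lower in the graft.

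THBS4, the matrix protein thrombospondin 4 named in the title of the series, rose from 0.237 ± 0.0978 FPKM in the controls to 62.8 ± 32.1 FPKM in the grafts of day 14 (log2 change 5.44, SE 0.38, adjusted p = 2.87e-09). All 4 grafts lay above all 4 controls (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 libraries allow). On both days this p assumes independent libraries, which nearly identical or mixture-like ones put in doubt. Graft replicates 1 to 4 held 15.3, 71.8, 78.6 and 85.5 FPKM of THBS4. The related THBS1 rose by 2.98 (SE 0.63, adjusted p = 0.000609), a call lost with control day 14 counted as 1 sample (adjusted p = 0.0532, within a range of 3.98e-08 to 0.126 over its alternatives). THBS3 rose by 0.64 (adjusted p = 0.000444), a call lost with both sample changes (adjusted p = 0.0963, range 1.71e-06 to 0.0963). THBS2 stayed under the filter on low values, and COMP and CNN1 were not found by name and were not analysed here.

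**Figure D2:**
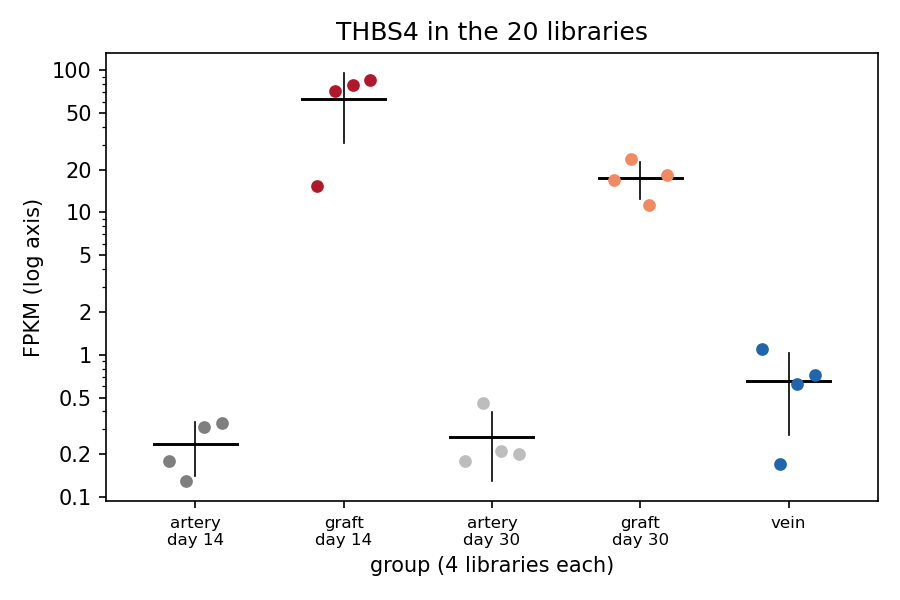
FPKM of THBS4 in each library of the 5 groups on a log axis, with the mean and SD of each group. Grafts of day 14 and day 30 average 62.8 and 17.5 FPKM, unoperated arteries 0.237 and 0.263 FPKM and vein 0.65 FPKM.

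Among the 8 largest rises at day 14 that the naming rule picked, HMOX1, heme oxygenase, reached 236 ± 201 FPKM, and ATP6V0D2, a subunit of the vacuolar proton pump, rose by 6.49 (SE 0.50) to 132 ± 77.6 FPKM. MMP9, a gelatinase, rose by 5.88 (SE 0.36). RLA-DR-ALPHA, a chain of the rabbit class II histocompatibility molecule, rose from 11.7 ± 0.95 to 569 ± 142 FPKM (log2 change 5.46, SE 0.32). TXN, thioredoxin, and CD68, a lysosomal protein of macrophages, were listed at 0 in all 4 controls. Grafts held 99.5, 86.0, 207 and 254 FPKM of TXN and 53.3, 45.7, 132 and 146 FPKM of CD68. Controls of day 30 averaged 107 FPKM of TXN, so its 0 can be a failed estimate. GUSB, a lysosomal glucuronidase, was listed at 0 in 3 controls and at 3.87 FPKM in replicate 3. The largest falls were those of BCHE, butyrylcholinesterase (-6.58, SE 0.30), CRYAB, a small heat shock protein that went from 2103 ± 89.8 to 31.4 ± 9.22 FPKM (-6.07, SE 0.24), and EPYC, a small proteoglycan (-6.07, SE 0.44). Also among the 8 largest falls were those of EFHD1 (-5.28), the protease inhibitor gene SPINK8 (-5.22), the integrin gene ITGA8 (-5.15), SUSD5 (-4.98) and P2RX1, an ATP-gated channel (-4.96).

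The lists of genes fixed before the data were examined moved as follows at day 14, where counts adjusted over the list alone are given only if they differ from those over all genes. The contractile list had a median log2 change of -2.93 (adjusted p = 2.08e-14). Falls were called for MYH11, the smooth muscle myosin heavy chain (-3.91), TAGLN, transgelin (-3.70), and MYLK, the kinase of the myosin light chain (-3.09). Ion channels and calcium handling followed, with 18 of 30 genes lower and 5 higher (median -0.98, adjusted p = 4.97e-06, or adjusted p = 0.0993 with an estimated correlation), among them PDE5A, which degrades cyclic GMP (-2.57), and the adrenergic receptor gene ADRA1B (-2.58). Of 23 cell cycle genes 0 fell, and 23 rose adjusted over the list alone (median 2.11, adjusted p = 1.86e-09). MCM6, part of the helicase that replicates DNA, rose from 1.32 ± 0.219 to 21.0 ± 5.49 FPKM, and CCNB1, a mitotic cyclin, rose by 3.30. The contractile genes that rose were TPM1, a tropomyosin (1.34), and HEYL, a target of Notch (1.22). Members named here for moving against their list were named after their values were seen.

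**Figure D3:**
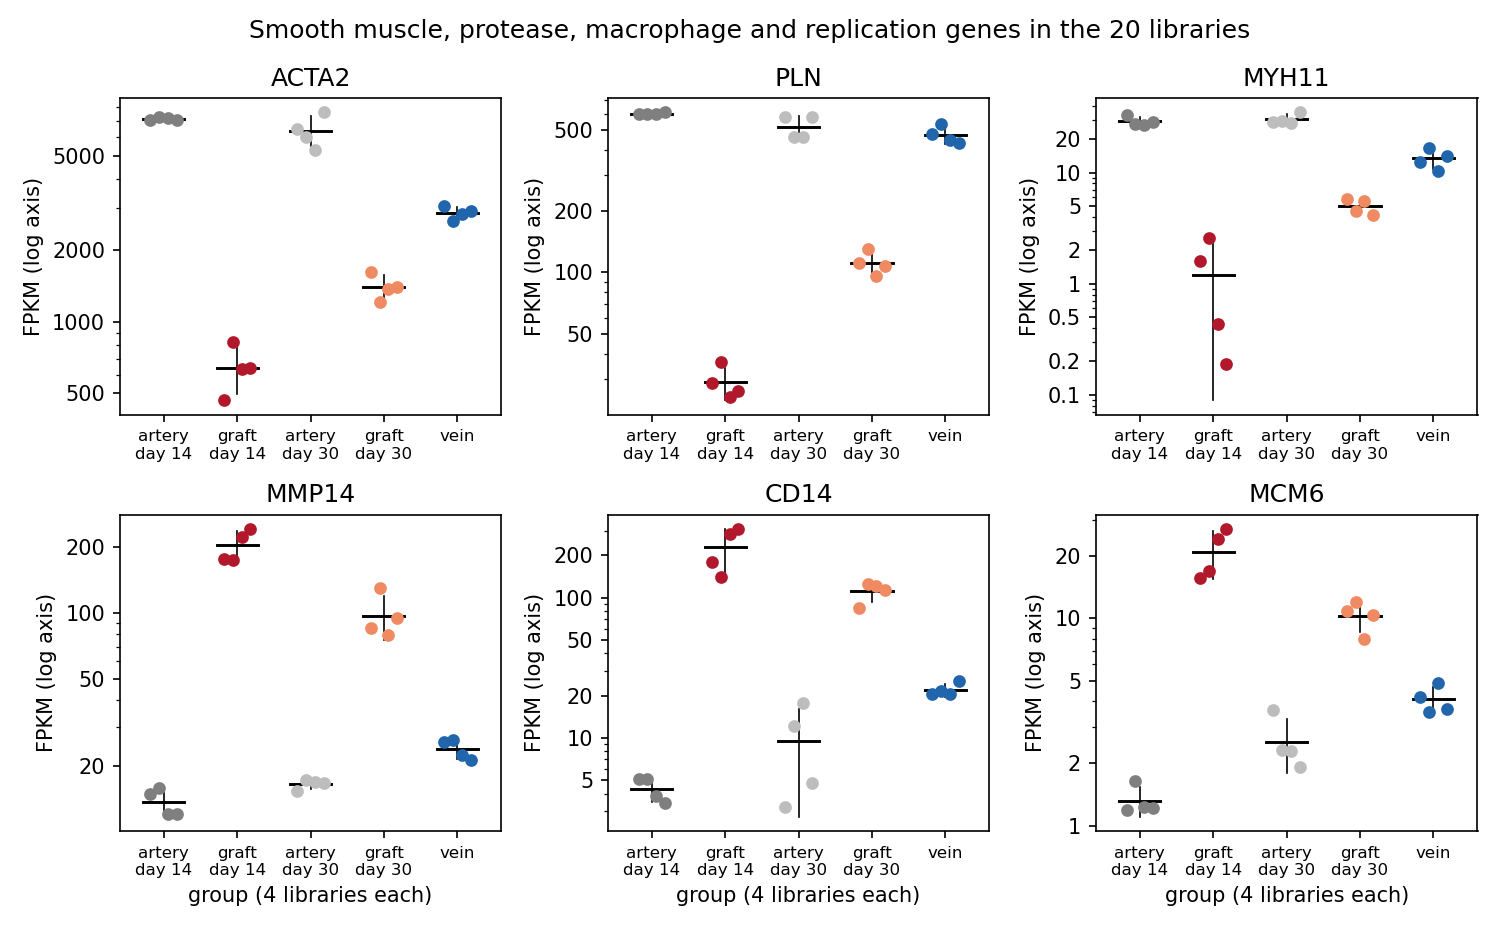
FPKM of ACTA2, PLN, MYH11, MMP14, CD14 and MCM6 in each library of the 5 groups on log axes, with the mean and SD of each group.

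Macrophage genes had a median of 3.34 (adjusted p = 2.68e-05), with 2 lower adjusted over the list alone. CD14, a receptor for bacterial lipopolysaccharide, rose from 4.34 ± 0.853 to 228 ± 80.6 FPKM, and FABP5, which binds fatty acids, rose by 5.37. CYBB fell by 0.70, and LYZ, lysozyme, from a mean of 36.7 to 6.0 FPKM. Lysosome and lipid handling genes rose in 19 of 27 cases, or 20 adjusted over the list alone, and fell in 1, LRP1 (median 1.49, adjusted p = 0.000913, or adjusted p = 0.432 with an estimated correlation), with GRN, progranulin, up by 3.65 and NR1H3, a sterol receptor, up by 2.60. T and natural killer cell genes rose in 8 of 10 cases, with CD3D, a part of the T cell receptor complex, up by 2.76 and CCR7 by 2.14. All 5 B and plasma cell genes rose, with JCHAIN, which joins antibody chains, up by 4.77. The tests gave adjusted p = 0.00995 for the T cell list and 0.0328 for the B cell list, and adjusted p = 0.417 and 0.284 with an estimated correlation. Both calls ended when genes listed at 0 in any library were left out (adjusted p = 0.163 for each). Of these 36 genes of the macrophage, T cell and B cell lists, 12 also averaged at least 1 FPKM in both groups of unoperated arteries, and 9 stand in another list too.

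Inflammatory cytokines and chemokines rose in 11 of 23 cases and fell in 0 (median 1.79, adjusted p = 0.0212, or adjusted p = 0.532 with an estimated correlation), among them CCL4, which attracts leukocytes (3.44), and the cytokine gene OSM (3.14). Interferon response genes rose in 11 of 19 cases (median 1.25, adjusted p = 0.0114, or adjusted p = 0.42 with an estimated correlation), with PSMB8, of the immunoproteasome, up by 3.14 and IRF9 by 1.34. Endothelial genes rose in 13 of 19 cases, or 14 adjusted over the list alone, and fell in 1, ESAM (median 1.18, adjusted p = 0.00414, or adjusted p = 0.513 with an estimated correlation). VWF, von Willebrand factor, rose from 7.02 ± 0.224 to 64.3 ± 23.0 FPKM and PLVAP, of the openings of capillary endothelium, rose by 3.54.

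Matrix proteases and inhibitors had a median of 1.69 (adjusted p = 0.00494). MMP14, a membrane collagenase, rose from 13.7 ± 1.98 to 204 ± 33.2 FPKM and ADAM12 rose by 4.58, while the inhibitor TIMP3 (-1.67) and the protease gene ADAMTS15 (-0.78) fell. Collagen genes rose in 11 of 18 cases and fell in 3 (median 1.00, adjusted p = 0.0321, or adjusted p = 0.483 with an estimated correlation), with COL1A2, a chain of type I collagen, going from 575 ± 10.3 to 2967 ± 490 FPKM. The collagen call ended without the 4 mixture-like libraries (adjusted p = 0.0558). The members that fell were COL14A1 (-2.75), LOX, which cross-links collagen (-0.83), and PLOD2 (-0.53). Proteoglycan genes fell in 9 of 14 cases and rose in 2 (median -0.65, adjusted p = 0.00814, or adjusted p = 0.265 with an estimated correlation), among them OGN, osteoglycin (-2.21). TGF-beta and BMP signalling genes fell in 12 of 33 cases and rose in 5 (median -0.57, adjusted p = 0.00327, or adjusted p = 0.135 with an estimated correlation), with BAMBI, a decoy receptor, down to 3.96 ± 1.71 from 108 ± 3.43 FPKM.

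Of 18 genes that promote apoptosis 15 rose and 1, RIPK1, fell (median 1.06, adjusted p = 0.00113, or adjusted p = 0.245 with an estimated correlation). The death ligand gene TNFSF10 rose by 2.63. BAX, which opens the outer membrane of mitochondria, rose by 1.62 (SE 0.22, adjusted p = 8.03e-06). Of 15 genes that restrain apoptosis 5 rose and 5 fell. The list did not pass (adjusted p = 0.208), while BCL2 itself fell by 1.85 (adjusted p = 6.51e-06).

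Nerve and Schwann cell genes fell in 8 of 11 cases and 1, MBP, rose (median -1.23, adjusted p = 1.64e-05, or adjusted p = 0.0599 with an estimated correlation). CDH19 and PRPH were listed at 0 in all 4 grafts. With genes listed at 0 in any library left out the nerve call ended (adjusted p = 0.163). Skeletal muscle genes fell in 3 of 4 cases (median -3.09, adjusted p = 0.0101, or adjusted p = 0.284 with an estimated correlation): CKM, the muscle creatine kinase, TNNC1, a troponin of slow and cardiac muscle (-4.86), and TCAP, a protein of the sarcomere. The osteochondrogenic list fell in 7 of 14 genes and rose in 2 (median -0.34, adjusted p = 0.0464, or adjusted p = 0.274 with an estimated correlation), with SOST, sclerostin, at -4.15 and COL11A1 at 3.95. That call ended without control day 14 replicate 1 (adjusted p = 0.0514) or 2 (0.0537), without graft day 14 replicate 1 (0.0539), 2 (0.0568) or 4 (0.0634), and after scaling by the median of ratios (0.111).

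At day 14, 17 lists did not pass (adjusted p from 0.0576 to 0.969). Members went both ways in matricellular proteins (10 of 20 higher and 6 lower) and in phenotypic modulation of smooth muscle (11 of 21 higher and 7 lower). TNC, tenascin C, rose by 2.88 and SPARCL1 fell by 3.64. Complement and coagulation had 6 of 13 higher and 5 lower (6 adjusted over the list alone), elastic fibre 4 of 11 higher and 5 lower, Wnt signalling 4 of 19 higher and 8 lower, and fibroblast and adventitia 2 of 15 higher and 6 lower. Arterial identity had 8 of 17 higher and 4 lower (9 higher adjusted over the list alone), and venous identity 10 of 17 higher and 3 lower (11 higher adjusted over the list alone). Lymphatic endothelium had 3 of 4 higher. Oxidative phosphorylation had 10 of 21 higher and glycolysis and hypoxia 12 of 25 higher and 3 lower (13 higher adjusted over the list alone). The stress response of the endoplasmic reticulum had 7 of 18 higher and 3 lower (8 higher adjusted over the list alone), basement membrane 3 of 11 higher and 3 lower (4 higher adjusted over the list alone), neutrophil and mast cell 5 of 9 higher, adipocyte 3 of 10 higher and 2 lower, and 0 of 2 erythroid genes passed. Median, mean and test differed in sign for Wnt signalling, fibroblast and adventitia, apoptosis restraining, complement, adipocyte and erythroid genes. The larger share of higher genes depends on scale: dividing by the median of ratios moved the median of all genes by 0.22 on the log2 scale and gave 2369 higher and 2140 lower genes, and quantile normalization gave 2192 higher and 2280 lower. After that shift the list medians were -3.22 for contractile, 2.00 for cell cycle, 3.06 for macrophage and 0.77 for apoptosis promoting genes.

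In 4333 genes, 50.1% of those tested, the grafts of day 14 and their controls did not overlap, where chance gives 2.86%. The count of 4634 became 4085 without the 4 mixture-like libraries, 2516 with control day 14 counted as 1 sample and 1671 with both changes.

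**Figure D4:**
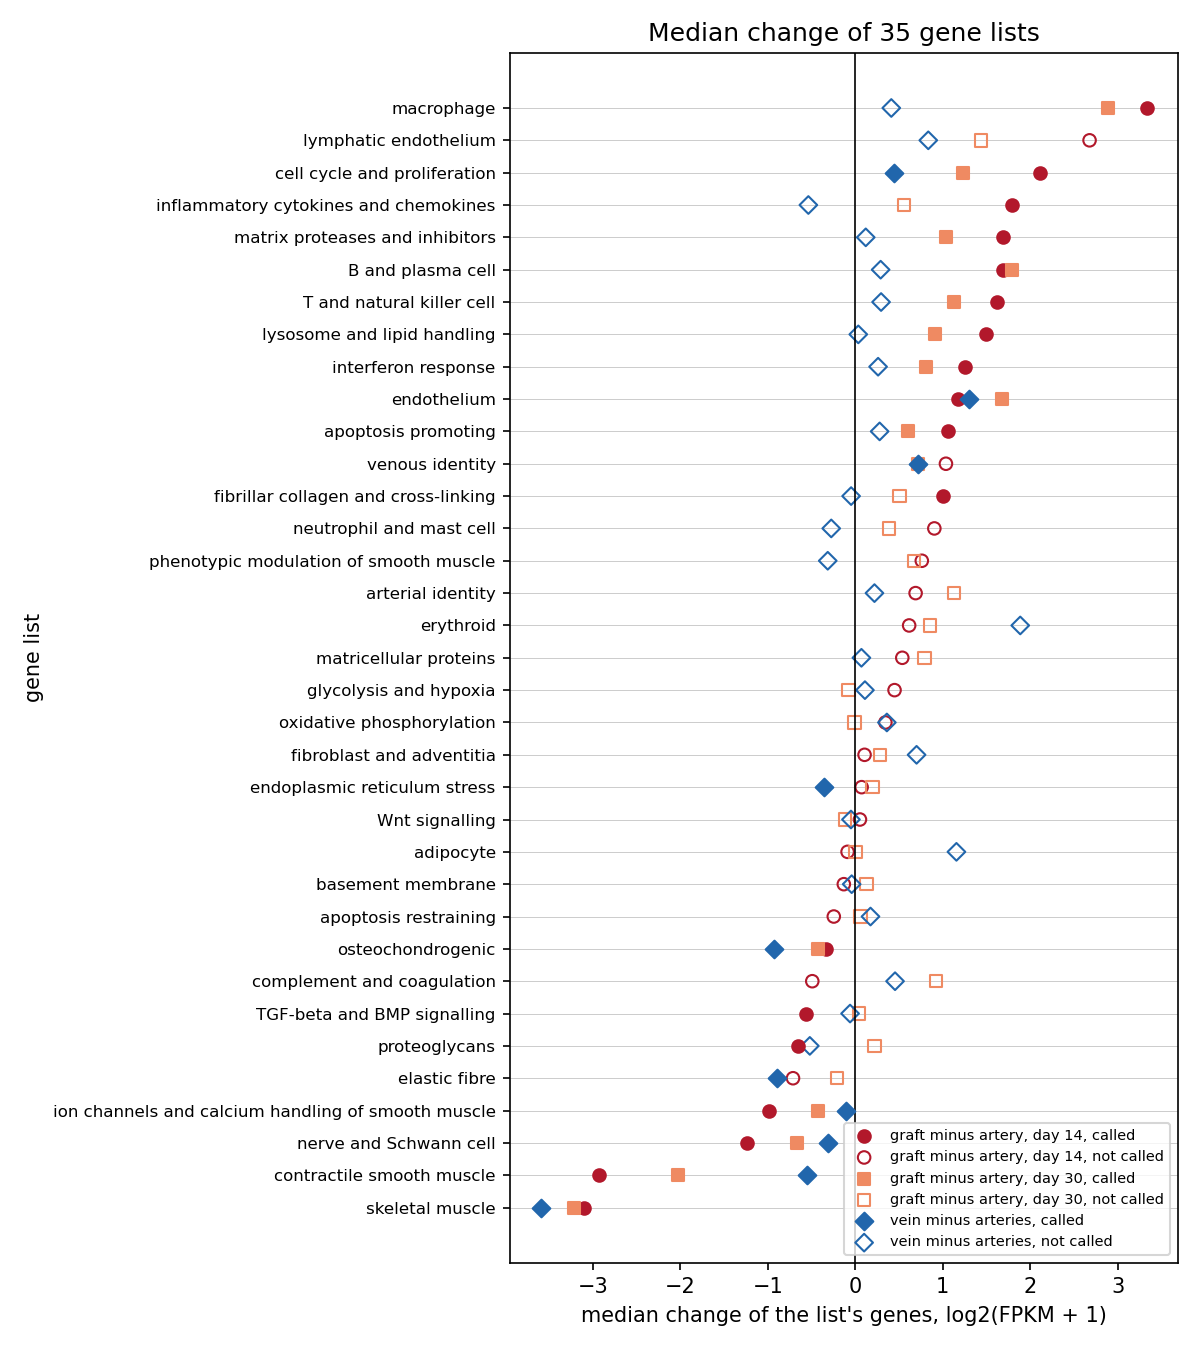
Median log2 change of each of the 35 gene lists in grafts of day 14 and of day 30 against unoperated arteries and in vein against unoperated arteries, with filled points where the list passed the test with the preset correlation. Contractile genes have medians of -2.93, -2.02 and -0.55 in the 3 comparisons.

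At day 30 the graft also differed from the opposite artery. MMP12 stood at 252 ± 147 FPKM in the grafts (log2 change 7.67, SE 0.30, adjusted p = 8.48e-12), and ACTA2 fell from 6347 ± 980 to 1401 ± 166 FPKM (-2.17, adjusted p = 5.6e-09). MMP14 rose from 16.5 ± 0.81 to 97.0 ± 22.2 FPKM (n = 4 in each group). THBS4 rose from 0.263 ± 0.132 to 17.5 ± 5.08 FPKM (log2 change 3.84, SE 0.38, adjusted p = 4.51e-07), again with all 4 grafts above all controls and a two-sided exact permutation p = 0.0286. The test called 3253 genes, 2253 higher and 1000 lower.

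Among the largest rises of day 30 were those of the mitochondrial transcripts ATP6, COX2, ND5 and ND4, which many other libraries list near 0. ATP6, a subunit of ATP synthase, was listed at 9305, 7099, 3.07 and 5608 FPKM in the grafts and at 2.44, 0.66, 2.33 and 1.37 FPKM in the controls. Its call ended without the 4 mixture-like libraries (adjusted p = 0.0753, range 1.62e-05 to 0.146). ND4, of complex I, was listed at 4.54, 219, 378 and 4.68 FPKM in the controls and 3243, 2616, 410 and 2212 FPKM in the grafts. Its call ended without control day 30 replicate 1 (adjusted p = 0.0992) or 4 (0.103) and without graft day 30 replicate 1 (0.0694), 2 (0.0693) or 4 (0.0661), within a range of 0.00692 to 0.148. The calls of COX2 and ND5 ended without the same libraries, and that of COX2 also without graft day 30 replicate 3 (adjusted p = 0.0575). Without the libraries common to both, the values ran from 0.068 to 0.133 (COX2) and 0.0632 to 0.117 (ND5). ATP6V0D2 rose by 6.27 (SE 0.50) and RLA-DR-ALPHA by 5.08 (SE 0.32). CD68 was listed at 0 in all controls and at 10.5, 112, 111 and 82.7 FPKM in the grafts. Among the largest falls were those of BCHE (-6.35, SE 0.30), PGM5, a relative of phosphoglucomutase at cell adhesions (-5.02), TNNC1 (-4.99), the Notch ligand gene DNER (-4.59, SE 0.15), MTUS2 (-4.49), ITGA8 (-4.42) and CRYAB, which went from 1489 ± 246 to 74.6 ± 19.8 FPKM (-4.33).

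Contractile smooth muscle genes fell in 21 of 29 cases and rose in 3 at day 30, or 22 and 4 adjusted over the list alone (median -2.02, adjusted p = 1.19e-15, and adjusted p = 0.0366 with an estimated correlation), the only list call in any comparison to hold with the estimate. Among those that fell were MYH11 (-2.38), TAGLN (-2.14), PLN (-2.20) and MYLK (-2.22). The members that rose, CALD1 (2.59), TPM1 (0.67) and HEYL (1.44), were named after their values were seen. Ion channels and calcium handling fell in 12 of 30 cases, or 13 adjusted over the list alone, and rose in 8 (median -0.43, adjusted p = 0.00327, or adjusted p = 0.321 with an estimated correlation), with KCNMB1, a subunit of a potassium channel, at 35.9 ± 3.54 against 122 ± 12.7 FPKM and the vasopressin receptor gene AVPR1A up by 1.95. Cell cycle genes rose in 20 of 23 cases, or 22 adjusted over the list alone (median 1.24, adjusted p = 1.84e-07, or adjusted p = 0.326 with an estimated correlation), with MCM6 up by 1.69 and the mitotic kinase gene PLK1 by 1.52.

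Macrophage genes rose in 15 of 21 cases, or 18 adjusted over the list alone (median 2.89, adjusted p = 2.09e-06, or adjusted p = 0.268 with an estimated correlation). Lysosome genes rose in 13 of 27, or 16 adjusted over the list alone (median 0.92, adjusted p = 0.000615, or adjusted p = 0.425 with an estimated correlation). FABP5 rose by 4.30, GRN by 2.31 and SCARB1, a lipoprotein receptor, by 2.56. T and natural killer cell genes rose in 8 of 10 cases (adjusted p = 0.00221) and B and plasma cell genes in 4 of 5 (adjusted p = 0.00862), or adjusted p = 0.326 and 0.268 with an estimated correlation. As at day 14, the filter favoured rises in both lists. JCHAIN went from 7.58 ± 4.77 to 252 ± 137 FPKM, MZB1, of antibody-secreting cells, rose by 2.71, CD3D by 2.20 and CD4, a coreceptor of helper T cells, by 1.55. With genes listed at 0 in any library left out, the T cell and B cell calls ended (adjusted p = 0.129 and 0.301). Interferon response genes rose in 12 of 19 cases (median 0.81, adjusted p = 0.0499, or adjusted p = 0.519 with an estimated correlation). The interferon call ended without control day 30 replicate 1 (adjusted p = 0.0545) or 4 (0.109), without graft day 30 replicate 3 (0.129) or 4 (0.0715), and with control day 14 counted as 1 sample (0.0548).

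Endothelial genes rose in 14 of 19 cases, or 15 adjusted over the list alone (median 1.68, adjusted p = 3.44e-05, or adjusted p = 0.363 with an estimated correlation). Venous identity genes rose in 9 of 17, with 2 lower (median 0.72, adjusted p = 0.0228, or adjusted p = 0.326 with an estimated correlation). VWF rose from 13.1 ± 4.95 to 132 ± 13.9 FPKM, PLVAP by 4.11, the apelin receptor gene APLNR by 3.91 and ACKR1, a chemokine receptor of venules, by 3.38. VWF and PLVAP stand in both lists, and 8 of the 17 venous genes stand in another list. Matrix proteases rose in 14 of 26 cases and fell in 3 (median 1.04, adjusted p = 0.00159, or adjusted p = 0.326 with an estimated correlation). Genes that promote apoptosis rose in 12 of 18 cases and 1, CYCS, fell (median 0.60, adjusted p = 0.00699, or adjusted p = 0.321 with an estimated correlation). TNFSF10 rose by 2.19, BCL2 fell by 1.06 (adjusted p = 0.00273) and BAX rose by 0.98 (adjusted p = 0.00189), a call that the TPM scale ended (adjusted p = 0.076, range 6.82e-06 to 0.076). The BCL2 call ended without the 2 control day 30 libraries high in inflammatory genes (adjusted p = 0.0514, range 4.24e-06 to 0.0737). THBS1 rose by 2.15 (adjusted p = 0.0113), not called when only the compared groups were fitted (adjusted p = 0.103, range 5.08e-07 to 0.103), and by 3.80 without the 2 control day 30 libraries high in inflammatory genes, while THBS3 rose by 0.90 (adjusted p = 2.89e-05).

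Nerve and Schwann cell genes fell in 6 of 11 cases (median -0.67, adjusted p = 0.000731, or adjusted p = 0.24 with an estimated correlation), among them GFAP, of glial filaments (-1.79). Skeletal muscle genes fell in 3 of 4 (median -3.22, adjusted p = 0.00221, or adjusted p = 0.268 with an estimated correlation). With genes listed at 0 in any library left out the nerve list did not pass (adjusted p = 0.13). The osteochondrogenic list had 5 of 14 lower and 2 higher, or 6 and 4 adjusted over the list alone (median -0.42, adjusted p = 0.0439, or adjusted p = 0.268 with an estimated correlation), with SOST at -3.90 and the cartilage gene CNMD at -3.67, listed at 0 in 2 grafts. Its call ended without control day 30 replicate 4 (adjusted p = 0.0555) or graft day 30 replicate 2 (0.0566), and after scaling by the median of ratios (0.101). The other 20 lists did not pass (adjusted p from 0.0773 to 0.915), among them collagen (10 of 18 higher and 3 lower), inflammatory cytokines (8 of 23 higher), arterial identity (10 of 17 higher and 3 lower, or 11 higher adjusted over the list alone) and matricellular proteins (10 of 20 higher and 4 lower, or 12 higher adjusted over the list alone). Median, mean and test differed in sign for proteoglycans, TGF-beta signalling, oxidative phosphorylation, apoptosis restraining, fibroblast and endoplasmic reticulum stress genes.

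Scaling by the median of ratios moved the median of all genes by 0.14 at day 30 and gave 1719 higher and 1451 lower genes, the TPM scale 1270 higher and 1256 lower, and quantile normalization 1482 higher and 1690 lower. After the shift the list medians were -2.16 for contractile, 1.09 for cell cycle, 2.71 for macrophage and 1.48 for endothelial genes. In 2983 genes, 34.5%, the groups did not overlap (chance 2.86% if all libraries are independent samples). The count of 3253 became 2379 without the 4 mixture-like libraries, 2919 with control day 14 counted as 1 sample, 1757 with both changes and 2716 without the 2 control day 30 libraries high in inflammatory genes.

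Day 14 and day 30 changes were alike across genes, with a Pearson correlation of 0.678 (jackknife SE 0.0398) and a Spearman correlation of 0.679 across 8657 genes, which are not independent replicates. Both days called 1816 genes higher, where independence would give 823, and 760 lower, where it would give 170, while 41 genes changed in opposite directions.

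The effect of grafting was compared between the days directly. Members of the cell cycle (11 of 23), glycolysis (8 of 25) and apoptosis promoting lists (3 of 18) had a lower effect at day 30, and contractile members (9 of 29, with 3 lower) a higher one. None of these list calls held with an estimated correlation (adjusted p = 0.402, 0.163, 0.418 and 0.381). The difference, day 30 minus day 14, was 2.14 for PLN (SE 0.17, adjusted p = 7.6e-07), 1.34 for ACTA2 (SE 0.21, adjusted p = 0.000595), -1.52 for MCM6 (SE 0.25, adjusted p = 0.000841) and -1.93 for LDHA, lactate dehydrogenase (SE 0.19, adjusted p = 1.06e-05), with n = 4 libraries in each of the 4 groups. THBS4 differed by -1.60 (SE 0.54, adjusted p = 0.0597), which did not pass. Without graft day 14 replicate 1 it differed by -2.17 and passed (adjusted p = 0.000153, range 1.5e-06 to 0.741). It also passed with genes at 5 FPKM or more (0.0497), with library weights (1.5e-06, or 0.033 by group) and without genes listed at 0 (0.0471). MYH11 and TAGLN differed by 1.53 (adjusted p = 0.00962) and 1.56 (adjusted p = 0.00705), both lost with control day 14 counted as 1 sample (0.185 and 0.149, in ranges of 2.56e-07 to 0.541 and 4.84e-06 to 0.452). BAX (-0.63, adjusted p = 0.197), BCL2 (0.80, 0.148), THBS1 (-0.83, 0.584) and THBS3 (0.26, 0.386) did not pass, though library weights gave 0.00685 for THBS1 and 0.00715 for THBS3, the lowest of ranges up to 0.968 and 0.903. THBS1 turned to 0.82 without the 2 control day 30 libraries high in inflammatory genes (adjusted p = 0.227).

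The difference was called for 1121 genes, 466 of them higher. Of the named genes ATP8, ND4L and ATP6 had the highest differences, followed by PDILT, a relative of protein disulfide isomerase (6.05, SE 0.71). ATP8, ND4L, ATP6, PRELP, LYZ and TXN were listed at or near 0 in some libraries. LYZ differed by 5.90, with grafts of day 30 at 278, 3.30, 1.60 and 73.4 FPKM and control means of 36.7 (day 14) and 1.42. Its call ended without the 4 mixture-like libraries (adjusted p = 0.097, range 1.02e-05 to 0.6). ATP8, ND4L and ATP6 lost their calls in the same way (adjusted p = 0.132, 0.14 and 0.145), as did PRELP (0.0554). ATP8 also did without any of the control day 14 replicates (0.052, 0.0512, 0.0519 and 0.0529), without control day 30 replicate 4 (0.0547) and without graft day 30 replicate 1 (0.0654), 2 (0.055) or 4 (0.0615). Without those same grafts the values were 0.0639, 0.0541 and 0.0602 for ND4L and 0.0627, 0.0525 and 0.059 for ATP6, and ND4L also lost its call without control day 14 replicate 4 (0.0513) and ATP6 without control day 30 replicate 2 (0.0507). Over all alternatives the adjusted p ran from 0.00023 to 0.639 (ATP8), 8.14e-05 to 0.653 (ND4L), 6.69e-05 to 0.657 (ATP6) and 5.38e-07 to 0.513 (PRELP).

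In the other direction SSPN, sarcospan, differed by -6.23 (listed at 0 in 3 of the controls of day 14), FAM83D, of the mitotic spindle, by -3.89, CTSE, a protease, by -4.47, HMOX1 by -4.22 and CXCL8, which attracts neutrophils, by -4.32, or -1.94 without control day 30 replicates 2 and 3 (adjusted p = 0.0684). The call of CXCL8 ended without any 1 of control day 14 replicates 1 to 4 or graft day 14 replicates 3 and 4. It also ended without control day 30 replicate 2 or 3 or graft day 30 replicate 2, 3 or 4. This call then had adjusted p from 0.0502 to 0.0688, within a range of 3.44e-06 to 0.693. That of HMOX1 ended without graft day 14 replicate 3 (adjusted p = 0.0537) or 4 (0.051), control day 30 replicate 2 (0.052) or graft day 30 replicate 4 (0.0504), within a range of 5.29e-07 to 0.691. Without the 4 mixture-like libraries CTSE lost its call too (adjusted p = 0.138, range 4.34e-06 to 0.645).

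Cell cycle genes had 15 lower differences adjusted over the list alone and 0 higher (median -0.83, adjusted p = 6.21e-08), with PCNA, of DNA replication, at -1.01. Glycolysis and hypoxia had a median of -0.70, with HIF1A, an oxygen-regulated factor, at -1.26, and oxidative phosphorylation had 8 of 21 lower, or 9 adjusted over the list alone (median -0.38). Contractile genes had 11 higher and 3 lower adjusted over the list alone (median 0.75), with CASQ2, which stores calcium, at 2.95. Ion channels had 8 of 30 higher and 1 lower, or 9 and 1 (median 0.49), and basement membrane 3 of 11 higher, or 6 (median 0.57), with LAMA2, a laminin chain, at 2.00. Each of these 5 lists had an adjusted p = 8.92e-05. TGF-beta signalling (4 of 33 higher, or 6 adjusted over the list alone), fibroblast genes (4 of 15 higher and 1 lower, or 6 and 1), collagen (3 of 18 lower, or 5), apoptosis promoting genes (3 of 18 lower, or 5 lower and 1 higher) and nerve genes (2 of 11 higher, or 3) also passed, with adjusted p = 0.00124, 0.0134, 0.0134, 0.0206 and 0.0206. With an estimated correlation none of these 11 calls held, with an adjusted p from 0.163 to 0.495.

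The fibroblast call ended without control day 30 replicate 4 (adjusted p = 0.0516), and the apoptosis and nerve calls without control day 30 replicate 3 (0.0592 and 0.138). Nerve genes had a median of -0.05 but a mean of 0.75, and with genes listed at 0 left out the list turned to lower (adjusted p = 0.898). The remaining 24 lists did not pass (adjusted p from 0.0557 to 0.96), and endoplasmic reticulum stress, arterial, phenotypic modulation, osteochondrogenic, skeletal muscle and matricellular genes differed in sign between median, mean and test. The split of 466 higher and 655 lower genes became 602 and 523 after scaling by the median of ratios, 288 and 269 on the TPM scale and 515 and 473 after quantile normalization. The count of 1121 fell to 381 without the 4 mixture-like libraries, 95 with control day 14 counted as 1 sample, where ACTA2 and MCM6 did not pass (adjusted p = 0.0553 and 0.0574, ranges 5.34e-09 to 0.387 and 5.93e-08 to 0.36), and 7 with both changes. PLN, SSPN and FAM83D passed in every alternative run on them.

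Grafts of day 30 were also set against those of day 14. F3, tissue factor, which starts coagulation, stood at 98.2 ± 42.4 FPKM on day 30 and 2.94 ± 0.249 FPKM on day 14 (log2 change 4.53, SE 0.32, adjusted p = 6.17e-08). EPYC stood at 47.6 ± 23.0 and 1.94 ± 2.01 FPKM (4.07, adjusted p = 1.21e-05), and PI16, a marker of adventitial fibroblasts, at 252 ± 37.7 and 32.4 ± 31.1 FPKM (3.63, adjusted p = 0.000537). ACTA2 rose by 1.15 (adjusted p = 6.97e-05), MYH11 by 1.58 and PLN by 1.92 (adjusted p = 2.59e-08). With replicate number as a block, 31 of the 34 named genes called between grafts did not pass, but no label pairs grafts across days. Those lost include ACTA2 (adjusted p = 0.123), EPYC (0.0873) and THBS3 (0.0888). With both sample changes 27 were lost, among them ACTA2 (0.0514) and THBS3 (0.0698). THBS4 was lower by -1.57 (SE 0.38, adjusted p = 0.00986), a call that ended on the TPM scale (adjusted p = 0.0727), with only the compared groups (0.136) and without the 4 mixture-like libraries (0.106), within a range of 5.02e-09 to 0.234.

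The test called 1412 genes, 693 higher and 719 lower on day 30. HP, haptoglobin, rose by 4.20, and the cytochrome P450 genes CYP2B4 and CYP2A10 by 3.98 and 3.61. The largest falls were those of CTSE (-2.91, listed at 21.9 FPKM in graft day 30 replicate 1 and at 0 in the others), HMOX1 (-2.60), SLC11A1, a metal transporter (-2.45), BARX1, a homeobox gene (-2.30), ANKRD37 (-2.17) and MMP3, stromelysin (-1.98). Without the 4 mixture-like libraries CYP2B4, CYP2A10, SLC11A1, BARX1 and ANKRD37 did not pass (adjusted p = 0.0608, 0.106, 0.0877, 0.0501 and 0.132), nor did TAGLN, up by 0.98 (0.107), VWF (0.0589) or ENG (0.0514). Over their alternatives these adjusted p ran from 1.25e-09 for ENG to 0.235 for CYP2A10 and ANKRD37. HP, PI16 and MYH11 did not pass with only the compared groups (0.053, 0.0528 and 0.0503), with ranges from 2.17e-10 for MYH11 to 0.132 for HP. CTSE did not pass without graft day 14 replicate 3 (adjusted p = 0.0622) or graft day 30 replicate 2, 3 or 4 (0.0615, 0.0696 and 0.0746), within a range of 3.91e-07 to 0.339. HMOX1 did not without graft day 14 replicate 3 or 4 (0.117 and 0.123) or graft day 30 replicate 1, 3 or 4 (0.0561, 0.103 and 0.103), within a range of 1.46e-07 to 0.395. MMP3 did not without graft day 14 replicate 3 or 4 (0.0782 and 0.0791) or graft day 30 replicate 2, 3 or 4 (0.0539, 0.0589 and 0.0501), within a range of 4.61e-08 to 0.31. THBS1 rose by 1.97 (adjusted p = 0.0406). It did not pass without any 1 graft of day 14 or without graft day 30 replicate 1, 3 or 4. These adjusted p were 0.0603 to 0.0974, within a range of 5.53e-05 to 0.285. THBS3 rose by 0.87 (adjusted p = 0.000297).

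Between the grafts, cell cycle genes fell in 15 of 23 cases, or 17 adjusted over the list alone (median -0.78, adjusted p = 5.5e-08), with MCM6 at -0.94 and CCNB1 at -1.15. Oxidative phosphorylation fell in 11 of 21, or 12 (adjusted p = 4.47e-06, UQCRQ -0.86 and COX5B -0.46). Glycolysis and hypoxia genes fell in 11 of 25 with 1 higher, or 11 and 2 (adjusted p = 0.00308), with TPI1 at 184 ± 8.99 against 352 ± 79.4 FPKM and LDHA at 162 ± 10.2 against 322 ± 65.7 FPKM. On the TPM scale MCM6, CCNB1, UQCRQ and COX5B did not pass (adjusted p = 0.076, 0.0588, 0.053 and 0.487), and over all alternatives their adjusted p ran from 1.52e-09 for UQCRQ to 0.487 for COX5B. Higher on day 30 were contractile genes (11 of 29, with 1 lower, adjusted p = 4.51e-06), basement membrane genes (7 of 11, or 8, adjusted p = 1.12e-06), with LAMA3 up by 1.65 and LAMA2 by 1.74, fibroblast genes (9 of 15, or 10, adjusted p = 2.36e-06), with MFAP5 up by 1.56 and SFRP4, a Wnt antagonist, by 2.04, and endothelial genes (7 of 19, or 8, adjusted p = 2.36e-06), with VWF up by 1.09 and ENG, endoglin, by 0.87. None of these 7 calls held with an estimated correlation (adjusted p from 0.0588 to 0.251).

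TGF-beta signalling (11 of 33, or 13 adjusted over the list alone, with BMP6 up by 1.34 and BMP2 by 0.99), ion channels (9 of 30 with 1 lower, or 12 and 2), complement (2 of 13), adipocyte (3 of 10, or 5), arterial identity (3 of 17), proteoglycan (4 of 14 with 1 lower, or 5 and 1) and venous identity genes (4 of 17, or 5 with 1 lower) were higher as well, with adjusted p of 1.78e-05, 9.63e-05, 0.0054, 0.00687, 0.00957, 0.0196 and 0.0288. With an estimated correlation these calls were lost too (adjusted p from 0.0588 to 0.408). The arterial call ended without graft day 14 replicate 4 (adjusted p = 0.0705), and the venous call without graft day 14 replicate 3 (0.0564) or 4 (0.121). The other 21 lists did not pass (adjusted p from 0.0508 to 0.924), and elastic fibre genes differed in sign between median, mean and test. The count of 1412 was 25 with the replicate number as a block, 828 on the TPM scale (750 higher and 78 lower), 918 without graft day 30 replicate 1, 321 with only the compared groups, 424 without the 4 mixture-like libraries and 88 with that change and control day 14 counted as 1 sample.

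In the unoperated arteries of day 30, set against those of day 14, 8 of 23 inflammatory genes were higher, and the list call rested on replicates 2 and 3 (adjusted p = 0.16 without them) and ended with an estimated correlation (0.816). PTGS2, cyclooxygenase 2, was listed at 36.3, 93.7, 166 and 15.1 FPKM on day 30 against 0.945 ± 0.273 FPKM on day 14 (log2 change 4.84, SE 0.69, adjusted p = 0.000248, n = 4). CCL2, which attracts monocytes, was listed at 12.2, 112, 182 and 8.05 FPKM against 1.15 ± 0.713 FPKM (4.27, SE 0.73, adjusted p = 0.00109). In replicates 2 and 3, the cytokine gene IL6 was listed at 111 and 225 FPKM, against 1.08 and 0.13 FPKM in replicates 1 and 4, and the adhesion genes SELE and ICAM1 were also highest in replicate 3, then 2. Replicate 2 is also the mixture-like library of its group.

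Inflammatory genes rose in 8 of 23 cases, or 12 with 1 lower adjusted over the list alone (median 1.89, adjusted p = 0.000163). Endothelial genes rose in 4 of 19, or 10 (median 0.61, adjusted p = 0.00108), and glycolysis and hypoxia genes in 5 of 25, or 6 (median 0.23, adjusted p = 0.0178). With an estimated correlation these calls were lost (adjusted p = 0.816, 0.816 and 0.762). Without replicates 2 and 3 of control day 30 the adjusted p were 0.16, 0.271 and 0.0797. SELP, P-selectin, rose by 2.47, OSM by 2.13, HIF1A by 0.85, LDHA by 0.96 and CALCRL, a peptide receptor of endothelium, by 1.65. With control day 14 counted as 1 sample none of these 5 passed (adjusted p = 0.324, 0.363, 0.0575, 0.143 and 0.247), nor did PTGS2 (0.132) or CCL2 (0.23). Over the alternatives of these 7 genes the adjusted p ran from 9.35e-09 for OSM, which also failed without replicates 2 and 3 (0.0777), to 0.992 for the same gene. THBS1 rose by 2.80 (adjusted p = 0.00748), at 10.1, 113, 210 and 21.2 FPKM on day 30, but by 1.14 without replicates 2 and 3 (adjusted p = 0.052, range 2.28e-06 to 1). THBS3 rose by 0.61 (adjusted p = 0.00555, or 0.0654 without these replicates, range 0.000144 to 0.935). THBS4 (0.03, adjusted p = 0.986), ACTA2 (-0.19, 0.476), TAGLN (-0.58, 0.148), BAX (0.12, 0.794) and BCL2 (-0.62, 0.129) did not pass, though library weights gave adjusted p = 0.0173 for ACTA2 and 0.0202 for BCL2, the lowest of ranges that reached 1.

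The test called 929 genes, 544 higher and 385 lower on day 30, which became 513 higher and 553 lower after scaling by the median of ratios, 846 and 137 on the TPM scale and 421 and 551 after quantile normalization. The count was 560 without control day 30 replicates 2 and 3, 433 without the 4 mixture-like libraries, 29 with control day 14 counted as 1 sample and 8 with both changes. The other 32 lists did not pass (adjusted p from 0.0759 to 0.99), and nerve, endoplasmic reticulum stress, apoptosis restraining, TGF-beta, skeletal muscle and Wnt genes differed in sign between median, mean and test.

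Endothelial genes were higher in vein than in the unoperated arteries in 14 of 19 cases, a call lost with an estimated correlation (adjusted p = 0.466). VWF stood at 441 ± 47.4 FPKM in vein, against 7.02 ± 0.224 and 13.1 ± 4.95 FPKM in the arteries of day 14 and day 30 (log2 change 5.40, SE 0.19, adjusted p = 1.03e-12, n = 4 in each group). RGS5, a brake on G protein signals in mural cells, stood at 11.6 ± 6.94 FPKM in vein against 3294 ± 32.1 and 2394 ± 418 FPKM (-8.07, SE 0.37, adjusted p = 2.23e-11). Of the contractile genes 14 of 29 were lower in vein and 1 higher, with ACTA2 at 2878 ± 176 FPKM (-1.22, SE 0.13, adjusted p = 6.76e-07). The test called 3214 genes, 2178 higher and 1036 lower.

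ENPP3 rose by 4.81, the homeobox gene SHOX2 by 4.73, ACKR1 by 4.43, GUCY1A2, of the nitric oxide receptor, by 4.35, the growth factor gene FGF7 by 4.16 and PLVAP by 4.15. RPS15A, of the ribosome, was listed at 0 in the arteries of day 14, and RPL5 at 0 in all vein libraries, so that neither change can be taken as a fold. ND4 was listed at between 0.99 and 3.77 FPKM in vein. Lower in vein were SUSD5 (-6.49), BCHE (-6.18), P2RX1 (-5.69) and HTR1B, a serotonin receptor (-5.43). THBS1 rose by 2.96 (adjusted p = 0.000314) and THBS3 by 0.89 (adjusted p = 7.32e-06). THBS4 (0.37, SE 0.33, adjusted p = 0.412) did not pass, except with only the compared groups (adjusted p = 0.0488, range 0.0488 to 0.721), and BAX (-0.17, 0.531) and TAGLN (-0.19, 0.525) did not, except TAGLN with library weights (-0.40, 0.0311). MYH11 (-1.10, adjusted p = 0.000657) and BCL2 (-0.85, adjusted p = 0.00501) fell, calls lost with both sample changes (0.0552 and 0.172).

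The endothelial list in vein had a median of 1.31 (adjusted p = 8.72e-06), with ENG up by 2.94 and EMCN, endomucin, by 3.99, and venous identity genes rose in 10 of 17 cases with 2 lower (median 0.72, adjusted p = 0.0115, or adjusted p = 0.292 with an estimated correlation). Contractile genes fell in 14 of 29 cases and 1, CASQ2, rose, by 2.92 (median -0.55, adjusted p = 1.13e-05, or adjusted p = 0.178 with an estimated correlation), with the integrin gene ITGA5 at -2.30. All 4 skeletal muscle genes fell (median -3.60, adjusted p = 0.000176), TNNC1 at -5.09. Endoplasmic reticulum stress genes fell in 7 of 18 cases with 1 higher, or 10 and 1 adjusted over the list alone (median -0.36, adjusted p = 0.000729), with the chaperone gene HSPA5 at -0.99 and CREB3L1 at 1.41. Nerve genes fell in 5 of 11 cases with 1 higher (median -0.31, adjusted p = 0.00178), CDH19 being listed at 0 in all vein libraries and all arteries of day 30. These 3 lists each had an adjusted p = 0.126 with an estimated correlation. The nerve call ended with genes listed at 0 left out (adjusted p = 0.341).

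Elastic fibre genes fell in 6 of 11 cases in vein with 2 higher (median -0.89, adjusted p = 0.00337), with FBN1, a fibrillin, at -0.89, LTBP2 at -1.91 and EMILIN2 at 2.80. Osteochondrogenic genes fell in 8 of 14 with 2 higher, or 9 and 2 adjusted over the list alone (median -0.93, adjusted p = 0.00178), with SOST at -3.48, ACAN, aggrecan, at -1.28 and the homeobox gene MSX2 at 2.64. Both lists had adjusted p = 0.0798 with an estimated correlation. Ion channels fell in 11 of 30 cases and rose in 8, or 13 and 9 adjusted over the list alone (median -0.11, adjusted p = 0.0296), and cell cycle genes rose in 10 of 23 (median 0.44, adjusted p = 0.0447), MCM3 by 0.79, with adjusted p = 0.511 and 0.766 with an estimated correlation. The channel call ended after scaling by the median of ratios (adjusted p = 0.0581). The cell cycle call ended without control day 14 replicate 2 (adjusted p = 0.0527), control day 30 replicate 1 (0.0558) or 4 (0.0529), or vein replicate 1 (0.111), 3 (0.0752) or 4 (0.0958).

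The other 25 lists did not pass in vein (adjusted p from 0.0925 to 0.99). Arterial identity had 4 of 17 higher and 5 lower, with TBX2 at -2.46 and EFNB2, an ephrin of arteries, at -1.54, and it differed in sign between median, mean and test, as did apoptosis restraining, basement membrane, protease, glycolysis, lysosome, matricellular and neutrophil genes. Scaling by the median of ratios moved the median of all genes by 0.12 and gave 1617 higher and 1527 lower genes, and quantile normalization gave 1601 and 1431. After that shift the list medians were 1.21 for endothelial, -0.72 for contractile and 0.58 for venous genes. In 2091 genes, 24.2%, vein and both artery groups did not overlap (chance 0.40% if all libraries are independent samples). The count of 3214 became 2333 without the 4 mixture-like libraries, 2051 with control day 14 counted as 1 sample and 1117 with both.

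Grafts were next compared with unoperated vein. At day 14 MMP12 was higher by 8.36 (SE 0.30), MMP14 by 3.03 and COL11A1, of cartilage and of remodelling matrix, by 4.10, at 20.9 ± 10.4 against 0.102 ± 0.0287 FPKM (n = 4). VWF was lower by -2.82, PLN by -3.99 and DCN, decorin, by -2.56, at 284 ± 43.4 against 1666 ± 37.3 FPKM. THBS4 was higher by 5.05 (adjusted p = 1.59e-08) and BAX by 1.73. ACTA2 was lower by -2.19, MYH11 by -2.83, TAGLN by -3.22 and THBS3 by -0.55 (adjusted p = 0.00232), THBS3 not passing with both sample changes (0.0503, range 2.03e-05 to 0.0503). THBS1 did not pass (-1.38, adjusted p = 0.0854), though it did with only the compared groups (0.00117), with library weights (0.00529), after quantile normalization (0.0475) and without the 2 control day 30 libraries high in inflammatory genes (0.00067), within a range of 0.00067 to 0.272. BCL2 was lower by -0.70 (adjusted p = 0.0322), a call that ended without graft day 14 replicate 1 (0.0921) or 2 (0.082) or vein replicate 1 (0.105), within a range of 0.0123 to 0.112.

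Against vein, cell cycle (22 of 23), macrophage (14 of 21, or 15 adjusted over the list alone), lysosome (20 of 27, or 22), protease (16 of 26 with 3 lower, or 17 and 3) and collagen genes (14 of 18 with 1 lower, or 15 and 1) were higher in grafts of day 14, with adjusted p of 2.27e-10, 6.56e-06, 6.56e-06, 1.85e-05 and 5.97e-05. LOXL1, which cross-links elastin, was higher by 1.18. Contractile genes (19 of 29 lower, 4 higher, adjusted p = 1.7e-08), fibroblast genes (9 of 15 lower, 1 higher, adjusted p = 5.32e-05) and ion channels (15 of 30 lower, 2 higher, adjusted p = 0.0015) were lower, as were nerve (7 of 11, with 1 higher), endothelial (8 of 19, with 3 higher), adipocyte (6 of 10, or 6 with 1 higher) and TGF-beta genes (10 of 33, with 4 higher). Apoptosis promoting (9 of 18, or 12), T cell (8 of 10, with 1 lower), endoplasmic reticulum stress (9 of 18, with 2 lower), B cell (3 of 5, or 4), inflammatory (11 of 23, or 12), arterial (6 of 17, with 1 lower) and interferon genes (8 of 19) were higher. These lists from nerve to interferon had adjusted p from 0.0108 to 0.0499. With an estimated correlation none of the 19 calls held (adjusted p from 0.243 to 0.576).

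Calls against vein ended without 1 library for endothelial genes (graft day 14 replicate 3, adjusted p = 0.0544, or 4, 0.0868), adipocyte and B cell genes (replicate 1, 0.05 for each), inflammatory genes (replicate 1, 0.075, or 2, 0.0596) and TGF-beta genes (replicate 4, 0.0735). They also ended for arterial genes (replicate 1, 0.063, or 2, 0.141, or vein replicate 1, 0.0699) and interferon genes (replicate 1, 0.175, or 3, 0.0508, or vein replicate 2, 0.0813, or 4, 0.0564). The other 16 lists did not pass (adjusted p from 0.0601 to 0.881), with differing signs for osteochondrogenic, matricellular and apoptosis restraining genes. The test called 3750 genes, 2239 higher and 1511 lower in the graft, a split that became 1093 and 1979 on the TPM scale and 1778 and 1931 after quantile normalization. The count was 2666 without the 4 mixture-like libraries and 2078 with both sample changes.

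At day 30, 13 of 17 arterial genes (2 lower) and 12 of 21 macrophage genes (1 lower) were higher in the graft than in vein, list calls lost with an estimated correlation (adjusted p = 0.18 and 0.246). TBX2, a transcription factor, was higher by 2.74, at 33.6 ± 8.45 against 4.06 ± 0.268 FPKM, GJA5, a connexin of arterial endothelium, by 4.26, at 31.4 ± 4.79 against 0.825 ± 0.963 FPKM, CXCR4, a chemokine receptor, by 3.29, MMP12 by 7.71 and COL11A1 by 2.95 (n = 4 in each group). PLN was lower by -2.07, ACTA2 by -1.04, MYH11 by -1.25 and TAGLN by -2.24. THBS4 was higher by 3.48 (adjusted p = 2.65e-06) and BAX by 1.22 (adjusted p = 0.000414), while THBS1 (0.59, adjusted p = 0.509), THBS3 (0.32, 0.0698) and BCL2 (-0.52, 0.124) did not pass. THBS3 passed with only the compared groups (0.036) and with library weights (0.000539, range 0.000539 to 0.401), and BCL2 after quantile normalization (0.014) and with library weights (0.004, range 0.004 to 0.385).

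Higher than in vein at day 30 were protease (18 of 26 with 1 lower), cell cycle (19 of 23, or 21 adjusted over the list alone), lysosome (15 of 27, or 17), macrophage, collagen (11 of 18, or 14), arterial identity (15 with 2 lower adjusted over the list alone) and inflammatory genes (12 of 23, or 19), with adjusted p of 4.99e-07, 5.8e-07, 1.92e-06, 6.56e-06, 3.84e-05, 8.79e-05 and 0.00025. B cell (4 of 5), T cell (8 of 10), endoplasmic reticulum stress (8 of 18 with 2 lower, or 9 and 2) and basement membrane genes (5 of 11 with 1 lower) were higher too, with adjusted p of 0.00233, 0.00314, 0.00809 and 0.0425. Contractile (18 of 29 with 4 higher, or 19 and 4), oxidative phosphorylation (8 of 21 with 1 higher, or 9 and 1) and nerve genes (6 of 11 with 1 higher, or 6 and 2) were lower, with adjusted p of 5.8e-07, 0.00772 and 0.0284. With an estimated correlation none of these 14 calls held (adjusted p from 0.18 to 0.463).

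Without graft day 30 replicate 2 the nerve call ended (adjusted p = 0.0745), and without graft day 30 replicate 1 (0.0985) or vein replicate 2 (0.0896) the basement membrane call. The other 21 lists did not pass (adjusted p from 0.0584 to 0.945), and proteoglycan, ion channel, venous, complement, neutrophil, Wnt and glycolysis genes differed in sign between median, mean and test. The test called 2894 genes, 1664 higher and 1230 lower in the graft, a split that became 1054 and 1198 on the TPM scale and 1269 and 1798 after quantile normalization. The count was 1918 without the 4 mixture-like libraries and 1286 with both sample changes.

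Whether grafts moved along the difference between vein and artery was examined across genes, with no control library shared between the sides. The change of day 14 correlated with vein minus the arteries of day 30 at a Pearson correlation of 0.295 (jackknife SE 0.0321, Spearman 0.267). The change of day 30 correlated with vein minus the arteries of day 14 at 0.289 (jackknife SE 0.0421, Spearman 0.406). Genes are not independent replicates, so no p-value is given. For day 14, 907 genes were higher and 481 lower on both sides, where independence would give 604 and 158, and 336 moved in opposite directions. For day 30, 1048 genes were higher and 481 lower on both sides, where independence would give 563 and 115, and 165 moved in opposite directions.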

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

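The tests of mixtures, transcripts near 0 and inflammatory control libraries were chosen after the result was seen, while those of other splits were planned.

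In 34 of 416 groups of 4 values (8.2%, by chance about 1 in 20) a library lay far from the rest of its group. In control day 14, replicate 3 held 3.87 FPKM of GUSB and 1.27 of SSPN (others 0), and 0.42 of TNFSF10 (others 1.66 to 1.84). Replicate 2 held 1.65 for MCM6 (others 1.19 to 1.23), 0.15 for CD3D (others 0) and 0.94 for SHOX2 (others 1.38 to 1.41). Replicate 1 held 0.68 for FAM83D (others 1.15 to 1.22). In graft day 14, replicate 2 held 12.42 for EFHD1 (others 4.48 to 4.96), 1.24 for ADRA1B (others 0.42 to 0.52), 0.26 for SOST (others 0 to 0.02) and 45.12 for MFAP5 (others 25.02 to 27.35). Replicate 1 held 15.35 for THBS4 (others 71.83 to 85.5) and 5.47 for COL11A1 (others 23.77 to 27.76), and ATP8 was listed at 0 in replicate 4.

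In control day 30, replicate 4 held 0.83 FPKM of CD4 (others 0.08 to 0.16) and 0.19 of GUCY1A2 (others 0.12 to 0.13). Replicate 2 held 0.46 of THBS4 (others 0.18 to 0.21) and replicate 1 held 0.19 of OSM (others 6, 7.81 and 6.80). In graft day 30, replicate 3 held 3.07 of ATP6, 9.92 of ATP8 and 0 of ND4L. Replicate 1 of these grafts held 10.47 of CD68 (others 82.68 to 112), 1.60 of BCHE (others 0.54 to 0.60), 21.86 of CTSE (others 0) and 0 of TXN (others 71.32 to 133.22). Replicate 2 held 31.14 of ACKR1 (others 40.47 to 41.57), 63.16 of HP, 0.30 of CYP2B4 (others 28.68 to 54.41) and 79.80 of MFAP5 (others 93.70 to 95.09). In vein, replicate 2 held 154.16 of EMCN (others 103.75 to 110.27), 33.46 of FBN1 (others 24.17 to 25.18), 87.81 of EMILIN2 (others 63.56 to 65.99) and 34.45 of LOXL1 (others 29.64 to 30.22). Replicate 1 held 3.12 of BCL2 (others 1.78 to 1.89).

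The effect of grafting differed between day 30 and day 14 for 39 of 81 named genes by limma's test of the difference (log2 scale). Many were named for this difference, so the share says nothing about genes at large, of which 1121 of 8657 passed. It was higher at day 30 for EPYC (3.59), CRYAB (1.74), EFHD1 (2.68), SPINK8 (1.28), SUSD5 (1.04), P2RX1 (2.83), PLN (2.14), MYLK (0.86), SPARCL1 (1.96), ACTA2 (1.34), MYH11 (1.53), TAGLN (1.56), ACKR1 (2.60), AVPR1A (1.96), PDILT (6.05), LYZ (5.90), CASQ2 (2.95) and LAMA2 (2.00), and for ATP6 (11.64) and ATP8 (14.03), which are near 0 in some libraries. It was lower for HMOX1 (-4.22), MCM6 (-1.52), CCNB1 (-1.57), CD14 (-1.71), CCR7 (-1.06), MMP14 (-1.34), ADAM12 (-1.71), GRN (-1.33), TNC (-1.77), OSM (-2.61), PSMB8 (-1.34), DNER (-1.84), SSPN (-6.23), CTSE (-4.47), CXCL8 (-4.32), FAM83D (-3.89), LDHA (-1.93), HIF1A (-1.26) and PCNA (-1.01). By camera, 11 of 35 lists differed, none with an estimated correlation (adjusted p from 0.163 to 0.495), with median differences of 0.75 (contractile), 0.57 (basement membrane), 0.44 (fibroblast), 0.37 (TGF-beta), 0.49 (ion channels), -0.27 (collagen), -0.45 (apoptosis promoting), -0.83 (cell cycle), -0.0497 (nerve, higher by camera, with a mean of 0.75), -0.38 (oxidative phosphorylation) and -0.70 (glycolysis).

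In 4 groups 1 library matched a weighted mean of the other 3, and if it held their material or values, a gene that 1 of them holds far above the rest would sit at that library's weight. For weights more than 0.15 from 0 and 1, 87.4% of 151 such genes lay within 0.15 of it in graft day 14 replicate 3, control day 30 replicate 2 and graft day 30 replicate 4 together, against 27.1% of 96 genes in other libraries, though the share was 57.1% at a weight of 0.1, where an absent gene counts too. Independent samples with intermediate levels need not keep to the weights. The lowest of the 3 libraries had 79.4% of its genes there, the higher of the 2 others 34.4%. This cannot decide where genes rise together, as inflammatory ones did in control day 30. A second library of 1 other sample would hold that sample's genes at its level, place 1, and the highest upper quartile of the place was 0.8454. Combined material or values stay possible. For vein replicate 4 these explanations cannot be told apart, since at most 6 genes were held by 1 library.

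Some transcripts, such as mitochondrial ATP8 and ATP6, were near 0 in some libraries and abundant in others. Less mitochondrial RNA in those libraries would lower COX1 and ND1 as well, and between the 10 libraries low in ATP8 and the other 10 these differed by -0.42 and 0.05 on the log2 scale (mean -0.1852), against -12.9 for ATP8. Too little depth is argued against by the smallest values listed, since the median value above 0 of 667 olfactory receptor transcripts was at most 0.24 FPKM in any library. Reads not assigned to these transcripts in the deposited values are a candidate explanation that stays open: RPL27, RPL5 and RPS15A, 3 of 51 ribosomal protein genes, were also at 0 in all libraries of a group and abundant elsewhere.

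Inflammatory genes were high in control day 30 replicate 3, where 18 of 23 lay at least 1 above the mean of replicates 1 and 4 on the log2 scale and the median was 2.98, while replicate 2 was high as well, with PTGS2 at 93.7 FPKM against 166 FPKM in replicate 3. A mislabelled graft is argued against, since over 1310 genes the library's median place between control, at 0, and graft, at 1, was 0.0876. Macrophages, T cells or B cells would raise their 36 genes, of which the unoperated arteries express 12, and the median difference of these was 0.0354. Neutrophils or mast cells cannot be told apart from other sources, since the median of their 9 genes was 0.8965 with 4 at least 1 higher and the arteries express 3 of the list. Apart from these cell types no biological explanation was tested, because no label separates this library from the rest of its group.

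In each of the 8 counts only 1 split, the real one, called as many genes. If libraries are independent samples, 35 or 100 splits make chance unlikely. The mixture-like and nearly identical libraries put this in doubt, and with both sample changes 7 (difference), 8 (between controls) and 88 genes (between grafts) remained. Among 35 splits of 8 libraries the highest other count was 3 against 4634 for graft and control of day 14, 26 against 3253 for day 30, 477 against 1412 between grafts, 2 against 929 between controls, 122 against 3750 for grafts of day 14 and vein, and 13 against 2894 for grafts of day 30 and vein. Among 100 splits it was 372 against 1121 for the difference between days and 6 against 2949 for vein and all controls as 1 group.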

How the results depend on the processing

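Alternatives dropping or merging libraries for likeness, dropping 2 control day 30 libraries or dropping genes listed at 0 were chosen after seeing the data. The others were planned. THBS4 kept its direction and its call against the controls on both days in every alternative. Its log2 change ran from 5.07 to 7.32 at day 14 and from 3.66 to 5.62 at day 30 over all alternatives, highest with the small pseudocount. With 1 library left out, it ranged from 5.21 to 6.01 at day 14 and from 3.69 to 4.02 at day 30, and the counts from 4307 to 4609 (day 14), 2864 to 3166 (day 30), 865 to 1405 (difference between days), 918 to 1658 (between grafts), 627 to 934 (between controls), 2756 to 3293 (vein), 3282 to 3861 and 2479 to 2733 (grafts of day 14 and day 30 against vein). List calls then ranged from 100 to 115 and the correlations from 0.27 to 0.306, 0.255 to 0.307 and 0.649 to 0.691.

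With control day 14 counted as 1 sample the counts were 2516 (day 14), 95 (difference), 29 (between controls) and 2051 (vein). Without the 4 mixture-like libraries they were 381 (difference), 424 (between grafts), 433 (between controls) and 1918 (day 30 against vein). With both they were 1671 (day 14), 1757 (day 30), 7 (difference), 88 (between grafts), 8 (between controls), 1117 (vein), 2078 and 1286 (grafts against vein). These settings leave fewer samples. Without 2 control day 30 libraries the count between controls was 560. The TPM scale gave 557 (difference) and 828 (between grafts), and only the compared groups gave 321 (between grafts). Library weights gave 5082 (day 30), 4257 (difference), 5299 (between grafts), 2963 (between controls), 5853 and 4655 (grafts against vein), with the highest weights, 11.6 and 6.01, on mixture-like libraries and without full convergence. Weights by group gave 757 (between grafts) and 1536 (between controls). A pseudocount of 0.1 gave a correlation of 0.253 between the change of day 14 and the vein difference. An estimated correlation left 1 of 104 list calls, and without genes listed at 0 the direction camera gave for the nerve list in the difference between days turned from higher to lower (adjusted p = 0.898). Apart from the fewer samples or genes, the cause was not tested.

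With the replicate number as a block (replicate block) the counts were 4270 (day 14), 2685 (day 30), 441 (difference), 25 (between grafts), 445 (between controls), 3498 (vein, or 3513 by library name), 2612 and 2409 (grafts against vein), THBS4 changed by 5.44 and 3.84, and 104 list calls were made. Whether equal numbers pair a graft with a control is not stated, and residuals of equal numbers correlated at 0.13, -0.08, -0.11 and 0.04 on day 14 and -0.04, -0.18, 0.06 and -0.04 on day 30, the best match in 1 of 4 on each day.

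Of 246 results of named genes, no called change turned its direction, though some uncalled ones did. Calls lost numbered 71 with both sample changes, 46 with the replicate block, 30 with control day 14 as 1 sample, 28 without the mixture-like libraries, 25 with only the compared groups, 10 on the TPM scale and 13 when 1 library was left out. Of 104 list calls, 27 were lost at 5 FPKM, 23 without genes listed at 0 and 18 when 1 library was left out. As depth is unknown, genes near 0 cannot be called absent.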
